A study of Zea mays with 6 samples.

How the data were processed

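RNA was measured by sequencing in endosperm of maize (Zea mays) harvested 10 days after pollination from wild-type (WT) plants and from the floury3 (fl3) mutant. There were 6 libraries in 2 groups, 3 of each genotype, which the design text calls independent biological replicates. Per the labels' protocols, field-grown plants were used, total RNA was extracted with TRIzol and a column kit, and libraries from an Illumina kit were sequenced on a HiSeq instrument. Each library has its own table of FPKM values (fragments mapped to a gene, scaled by its length and the library total), as the authors deposited it. The submitters' processing notes name FastQC, TopHat and Bowtie2 and the genome build B73 RefGen_v3, with no role or order. The tool that computed the FPKM values, the annotation and the use of strand are not given in the sources used here.

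The tables hold the same 39448 gene identifiers in the same order. The values do not fall into steps of whole reads. Among low genes, the ratio of WT replicate 1 to another library lay within 1% of its most frequent value for at most 6.09% of genes. Read counts were therefore not recovered, sequencing depth stayed unknown, and no interval for counting error is given. The planned count-based tests were not run for the same reason. FPKM values summed to between 465741 and 480602 per library. No 2 tables were identical.

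Gene names came from an NCBI RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, matched on identifiers and synonyms. Of the 39448 identifiers, 18906 matched, 521 of them to more than 1 reference gene, and 2625 had an informative name. Because that assembly differs from the build of the files, it was used for names, chromosome and gene order, and none of its coordinates are given.

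Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 17272 in all, of which 1697 (9.8%) had an informative name. log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with genotype as the only term. Two-sided p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are said to have risen or fallen. Every log2 fold change is fl3 minus WT on the log2(FPKM + 1) scale, which understates the change of genes with low values. Folds given as such are ratios of mean FPKM. On simulated data for this comparison with 17272 genes, the fit recovered 61% of 100 genes changed by 0.5 and 93% of 100 genes changed by 1 on the log2 scale, and called 0.07% of 17072 unchanged genes. The changed genes were drawn from those of higher WT level, with equal numbers up and down and normally distributed noise. In the real data 67.3% of tested genes were called, so these rates do not carry over to them.

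Single quantities, such as the zein share, were compared with exact two-sided permutation tests in SciPy 1.17.1. With 3 libraries against 3 their smallest possible p is 0.1, so they cannot pass the threshold. Gene lists were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes, and with an estimated correlation and fry beside it. The Benjamini-Hochberg adjustment ran over the 18 lists with at least 5 measured members. List topics were fixed before the data were examined, along with the tests, alternatives and naming rule. The lists had been written as searches of gene descriptions, which the reference table lacks, so symbols were assigned to the same topics after the files had been opened. Lists for RNA polymerases I and II, tRNA synthetases and tRNA modification, ribosome biogenesis, mitochondrial respiration and the proteasome found no symbols and were not analysed here. The RNA polymerase III list came down to the factor TFIIIA, and the PLATZ list to 2 measured genes.

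The genes named follow a rule. They are the floury3 gene, the 12 highest-rising and 12 deepest-falling named genes with no overlap between genotypes and a mean of at least 5 FPKM, up to 4 members per list by size of change, and named genes among the 10 of highest mean. At most 2 identifiers without a name are given per direction. Genes named outside this rule are marked as chosen after their values were seen.

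Called and other genes were compared per chromosome with Fisher's exact test, and windows of 50 neighbouring tested genes with 1000 shuffles of the calls. Alternatives covered the pseudocount, the filter, 4 ways of scaling, the variance model, library weights, the replicate number as a block, and leaving out each library in turn. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.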

Results

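The data are FPKM values of 39448 genes in 3 WT and 3 fl3 libraries of maize endosperm, the starch- and protein-storing tissue of the kernel, sampled 10 days after pollination. The floury3 mutation gives kernels a soft, opaque endosperm, and the gene encodes a PLATZ protein, a plant-specific zinc-binding factor that interacts with RNA polymerase III factors. Between 23808 and 24755 genes had a value above 0 per library. Correlations of log2(FPKM + 1) over the 17272 tested genes were 0.992 to 0.995 among WT libraries, 0.988 to 0.991 among fl3 libraries and 0.895 to 0.900 between genotypes; these run across genes, which are not independent replicates. The limma p-values of single genes below set the difference between genotypes against the spread between these 6 libraries. Camera sets a list against other genes. Fisher's exact tests, window shuffles and permutation tests over genes take genes as units, which are likewise not independent.

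The comparison of fl3 with WT asks how the endosperm transcriptome of the mutant differs. Transcripts of the floury3 gene itself (GRMZM2G006585) were higher in fl3, at 3158 ± 67.3 FPKM (SD, n = 3) against 2260 ± 164 FPKM in WT, and every fl3 library lay above every WT library (log2 fold change 0.48, SE 0.09, adjusted p = 0.00146 by limma). The exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. The rise was 0.32 on the log2 scale under median-of-ratios scaling and 0.93 under quantile normalization, with the call kept in each. In the same fit 7519 genes rose and 4107 fell, together 67.3% of the tested genes, and 2461 changed at least 2-fold, 1743 upward and 718 downward. The genotypes did not overlap for 71.7% of tested genes, where chance gives 10%. The median log2 fold change over all tested genes was 0.14, and median-of-ratios scaling brought it to 0.002; the split of calls then moved from 64.7% higher to 50.4% higher (5841 up, 5758 down), with quantile normalization giving 48.3%. Medians of gene lists are to be read against that shift, and counts of risen and fallen members of lists and families against 7519 and 4107 of 17272 tested genes.

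Transcripts of zeins, the prolamin storage proteins of the maize kernel, fell in fl3, with the lowest median of the 18 lists tested. Of 23 measured zein genes 22 fell, 0 rose and 1 did not pass, with 22 falling also when adjusted over the list alone and a median log2 fold change of -2.71; under quantile normalization 20 fell and 1 rose. The 22-kDa alpha-zein gene z1C1_4 (GRMZM2G044625) fell from 1904 ± 308 to 32.7 ± 11.3 FPKM (SD, n = 3), a 58.2-fold difference of means (log2 fold change -5.87, SE 0.24, limma adjusted p = 3.33e-07), and z1C1_8 (GRMZM2G044152) fell from 985 ± 182 to 27.1 ± 12.4 FPKM. The alpha-zein genes in which the floury2 and floury4 mutations lie, z1C2 (GRMZM2G397687) and z1A1_6 (GRMZM2G353272), were 14.9-fold and 21.4-fold lower. The beta-zein bz15 (GRMZM2G086294) fell from 6771 ± 476 to 2158 ± 394 FPKM.

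The gamma-zeins gz27 (GRMZM2G138727), the highest of all named genes, and gz16 (GRMZM2G060429) fell less. Means went from 14122 ± 1400 to 8630 ± 1372 FPKM for gz27 and from 3714 ± 652 to 2097 ± 429.7 FPKM for gz16. Under quantile normalization the fall of gz16 did not pass (log2 fold change -0.37). That method gives the highest gene of each library the same value, so the 0.00 of gz27 there cannot bear on its fall. Without the filter on low values gz27 kept its log2 fold change of -0.72 but did not pass (adjusted p = 0.149 by limma). The delta-zein dzs18 (GRMZM2G100018), named after its values were seen, had 504 ± 36.9 FPKM in WT and 624 ± 145 FPKM in fl3 (limma adjusted p = 0.131). Its rise passed under quantile normalization and without fl3 replicate 1. Summed over the named genes, z1C transcripts went from 4586 ± 749 to 169.9 ± 55.4 FPKM and z1A transcripts from 9093 ± 1648 to 1113 ± 340 FPKM. The median log2 fold change was -4.21 over 10 z1C genes and -2.60 over 8 z1A genes. An exact permutation test of the difference of their means did not pass (p = 0.115). It ran over genes, which are not independent. All named zeins together made up 8.14% ± 0.997 of the FPKM sum in WT and 3.13% ± 0.517 in fl3 (SD, n = 3; exact permutation p = 0.1, the smallest possible). Camera called the zein list lower than other genes (adjusted p = 2.12e-12, limma), but not with an estimated correlation (adjusted p = 0.933 with an estimated correlation); the correlation estimated among zeins was 0.776. Alpha-zeins are near-identical copies, so the FPKM of a single copy is uncertain, and zein genes without a name in the reference table are not counted.

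**Figure D1:**
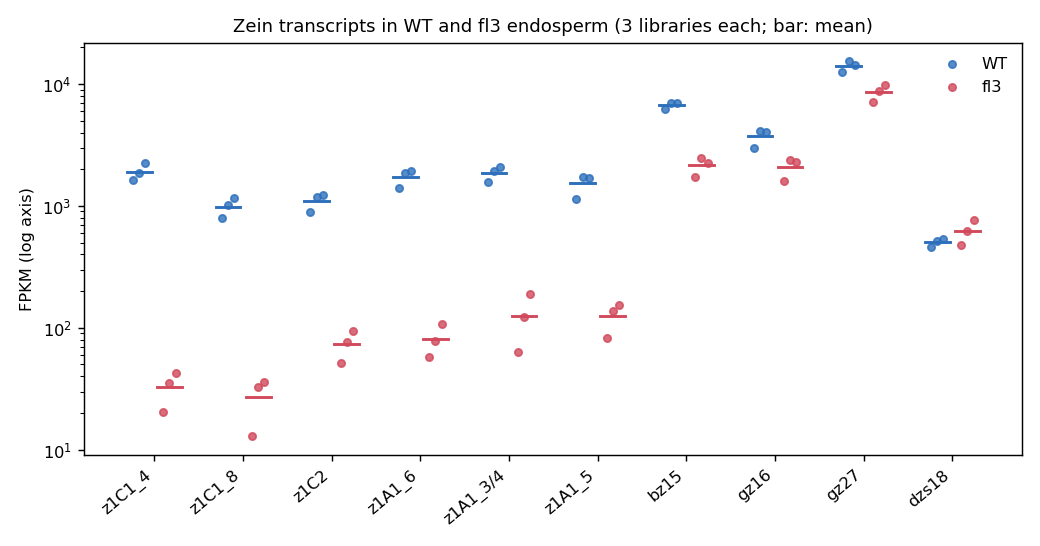
FPKM of 10 zein genes on a log axis, with 1 point per library, WT in blue and fl3 in red, and bars at the group means of 3 libraries. The alpha-zeins z1C1_4 to z1A1_5 lie far lower in fl3, gz27 falls from a mean of 14122 to 8630 FPKM, and dzs18 overlaps between genotypes.

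Regulators of storage genes went both ways, 4 up, 6 down and 3 not passed of 13, with the same counts adjusted over the list alone and 2 up and 6 down under quantile normalization. Prolamin-box binding factor pbf1 (GRMZM2G146283) fell 2.27-fold from 79.5 ± 9.43 FPKM and the bZIP activator of alpha-zein genes o2, opaque2 (GRMZM2G015534), from 67.3 ± 3.61 to 32.5 ± 5.70 FPKM (SD, n = 3), with limma adjusted p of 2e-05 and 8.07e-05. NRP1 (GRMZM2G062650) fell from 413 ± 15.4 to 196 ± 32.7 FPKM. Floury1 (GRMZM2G094532), a protein-body membrane protein, rose from 6.71 ± 0.562 to 11.1 ± 0.869 FPKM. A second identifier matched to pbf1 (GRMZM2G146267), named after its values were seen, rose by a log2 fold change of 0.23, so reads split between these models are uncertain. Camera did not call the list (adjusted p = 0.364, limma).

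Genes of starch synthesis split into 7 that rose, 10 that fell and 5 that did not pass, the same when adjusted over the list alone. The granule-bound starch synthase wx1, waxy (GRMZM2G024993), fell from 215 ± 8.66 to 58.8 ± 9.57 FPKM, and the ADP-glucose pyrophosphorylase subunit Agpsemzm (GRMZM2G106213) from 168 ± 10.2 to 45.3 ± 2.24 FPKM (SD, n = 3; log2 fold change -1.87 for each, limma adjusted p = 2.2e-06 and 1.58e-07). Sucrose synthase sh1 (GRMZM2G089713) fell from 1481 ± 70.2 to 722 ± 53.3 FPKM, and bt2 (GRMZM2G068506), bt1 (GRMZM2G144081) and sh2 (GRMZM2G429899), which act in making and importing ADP-glucose, had log2 fold changes of -0.91, -0.86 and -0.66; these 4 were chosen after their values were seen. The debranching enzymes zpu1 (GRMZM2G158043) and iso3 (GRMZM2G150796) rose from low levels, by log2 fold changes of 1.30 and 1.17. Camera did not call the list (adjusted p = 0.127, limma). Under median-of-ratios scaling 6 members rose and 13 fell, and under quantile normalization 5 and 12.

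Markers of the embryo-surrounding region, the endosperm cells that line the young embryo, were higher in fl3 for 5 of 5 measured genes, over all genes and adjusted over the list alone, with a median log2 fold change of 2.11. ESR3 (GRMZM2G140302) rose from 10.6 ± 2.33 to 82.7 ± 21.7 FPKM (SD, n = 3; log2 fold change 2.84, SE 0.19, limma adjusted p = 4.2e-06), and esr1 (GRMZM2G046086) rose from 19.1 ± 2.84 to 86.7 ± 19.6 FPKM. The gene ae3 (GRMZM2G372553) rose 16.1-fold from a mean of 0.688 FPKM, and esr6 (GRMZM2G048353) rose 2.86-fold. Camera called the list (adjusted p = 0.0235, limma) but not with an estimated correlation (adjusted p = 0.933 with an estimated correlation). Some ESR genes are close copies, so reads split between them are uncertain.

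Other compartments moved less as groups. Of 16 basal transfer layer markers, genes of the cells that take up maternal nutrients, 4 rose, 1 fell and 11 did not pass, or 3 and 1 adjusted over the list alone. The counts and the sign of the median (0.12) depended on single libraries. There were 3 up and 3 down without fl3 replicate 2 (median -0.18) and 2 up and 2 down without WT replicate 3 (median -0.04). Without fl3 replicate 3 there were 5 up and 1 down (median 0.37). The marker betl3 (GRMZM2G175976) rose from 4.92 ± 0.568 to 25.9 ± 15.8 FPKM and bap-1a (GRMZM2G008271) fell from 77.4 ± 23.5 to 12.3 ± 6.97 FPKM. These markers varied within genotypes, with a mean log2(FPKM + 1) of 6.72 in WT replicate 3 and 6.66 in fl3 replicate 3 against 7.69 in fl3 replicate 2, and group means of 6.99 ± 0.243 and 7.14 ± 0.516 (exact permutation p = 0.8, n = 3). With that mean as a covariate, a setting chosen after the data were seen, 7299 genes rose and 3991 fell. Of 14 listed embryo genes 7 were measured, of which 3 rose, 1 fell and 3 did not pass, at a median of 0.23 that ran from 0.15 to 0.40 without 1 library at a time. Of the called embryo genes, vp1 (GRMZM2G133398) changed most, rising from 1.56 ± 0.153 to 3.70 ± 0.579 FPKM (log2 fold change 0.87). The oil-body oleosin ole1 (GRMZM2G337229) rose from 139.8 ± 9.35 to 219 ± 16.0 FPKM and the globulin glb3 (GRMZM2G410134) fell from 233 ± 21.0 to 169 ± 18.7 FPKM. Of 6 aleurone genes 2 rose, 1 fell and 3 did not pass, or 2 and 0 adjusted over the list alone, and 2 up and 3 down under both median-of-ratios scaling and quantile normalization. The receptor kinase cr4 (GRMZM2G051637) rose from 4.65 ± 0.503 to 15.7 ± 0.542 FPKM. Camera adjusted p was 0.839, 0.816 and 0.928 for these lists (limma). All 18 listed genes of green maternal tissue were below the filter, with no group mean above 0.66 FPKM.

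**Figure D2:**
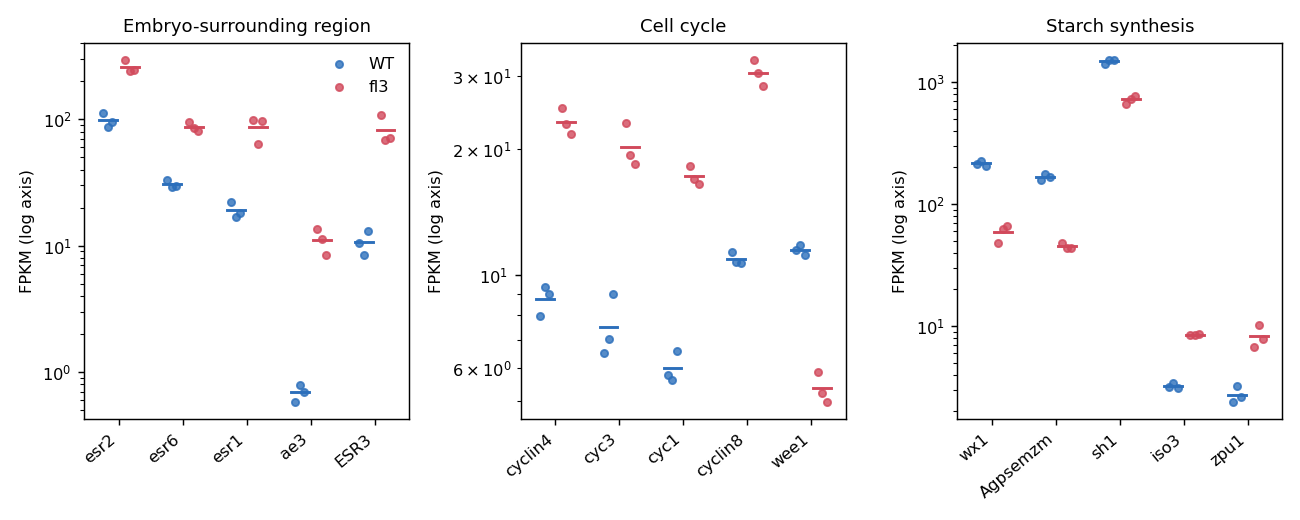
FPKM on log axes of embryo-surrounding region, cell-cycle and starch synthesis genes, with 1 point per library, WT in blue and fl3 in red, and bars at the means of 3 libraries. The genotypes do not overlap for any gene drawn; wx1 falls from a mean of 215 to 58.8 FPKM and ESR3 rises from 10.6 to 82.7 FPKM.

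Of 10 cyclins and cell-cycle kinases 8 rose, wee1 (GRMZM5G878541, named after its values were seen) fell and 1 did not pass, the same adjusted over the list alone, at a median log2 fold change of 0.96, but camera did not call the list (adjusted p = 0.127, limma; 0.933 with an estimated correlation). The cyclins cyclin8 (GRMZM2G138886), cyc1 (GRMZM2G034647), cyc3 (GRMZM2G073671) and cyclin4 (GRMZM2G310115) rose, by log2 fold changes of 1.40, 1.39, 1.33 and 1.31, cyclin8 from 10.9 ± 0.368 to 30.5 ± 2.22 FPKM (SD, n = 3). DNA replication genes showed 4 up, 6 down and 5 not passed. Small subunits of ribonucleotide reductase, the enzyme that makes deoxynucleotides, moved apart: RNRS2 (GRMZM2G155546) rose from 3.31 ± 0.552 to 23.5 ± 1.12 FPKM, while RNRS1 (GRMZM2G060163) fell from 80.5 ± 6.67 to 44.4 ± 4.39 FPKM. Core histones had 5 up, 3 down and 6 not passed, with his2b5 (GRMZM2G342515) up by 0.64 and an H4 gene (GRMZM2G084195) at -0.51 on the log2 scale.

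Auxin genes were 12 up, 6 down and 8 not passed of 26. The flavin monooxygenase yuc (GRMZM2G091819), of the family that makes auxin, rose from 100.1 ± 1.86 to 587 ± 50.4 FPKM (SD, n = 3), a 5.87-fold difference (limma adjusted p = 6.85e-08), and Yucca6 (GRMZM2G019515) rose from 16.9 ± 0.876 to 49.0 ± 2.24 FPKM. TAR3 (GRMZM2G141810), of the aminotransferase family upstream in the same pathway, fell from 167 ± 2.72 to 31.6 ± 7.39 FPKM. Protein folding genes of the endoplasmic reticulum were 12 up, 5 down and 6 not passed, or 13 and 5 adjusted over the list alone, 9 up and 8 down under median-of-ratios scaling, and 9 up and 5 down under quantile normalization. The disulfide isomerase pdi2 (GRMZM2G163421) rose from 13.0 ± 0.573 to 49.8 ± 7.72 FPKM and the calreticulin crt2 (GRMZM2G358059) from 111 ± 5.23 to 198 ± 2.71 FPKM. The chaperone gene bip1 (GRMZM2G114793), named after its values were seen, had 127.6 ± 8.81 FPKM in WT and 120.0 ± 4.32 FPKM in fl3 (limma adjusted p = 0.26). Heat shock genes were 6 up and 5 down, with hsp22 (GRMZM2G007729) up 2.78-fold and hsp18c (GRMZM2G034157) down from 3.92 to 0.248 FPKM.

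The remaining lists held members moving each way. Cytosolic ribosomal proteins were 13 up, 12 down and 13 not passed of 38, and 7 up and 19 down under median-of-ratios scaling but 14 up and 15 down under quantile normalization. The gene rps6 (GRMZM2G054136) rose from 27.5 ± 5.25 to 56.5 ± 1.22 FPKM. Translation factors were 5 up, 4 down and 4 not passed, and turned with the scaling, 3 up and 8 down under median-of-ratios scaling but 6 up and 2 down under quantile normalization, with GOS2 (GRMZM5G835323) up from 26.4 ± 4.49 to 50.3 ± 3.58 FPKM. Glycolysis genes were 1 up, 4 down and 7 not passed, 1 up and 9 down under median-of-ratios scaling, and 3 up and 5 down under quantile normalization. The aldolase ald1 (GRMZM2G057823) fell from 2446 ± 172 to 1323 ± 44.9 FPKM and a low enolase gene (GRMZM2G009030) rose 2.33-fold. Sugar import and cleavage genes were 2 up, 1 down and 4 not passed, 2 up and 4 down under median-of-ratios scaling, and 3 up and 3 down under quantile normalization, with the cell-wall invertase incw1 (GRMZM2G139300) up from 2.09 ± 0.410 to 7.61 ± 0.248 FPKM. Defense and protease inhibitor genes were 5 up, 5 down and 9 not passed, and 5 up and 8 down without fl3 replicate 2, with a Serpin-Z1 gene (GRMZM2G066996) up from 19.5 ± 0.626 to 72.4 ± 5.62 FPKM and cystatin cc10 (GRMZM2G030717) down from 67.6 ± 9.97 to 18.4 ± 4.89 FPKM. The RNA polymerase III factor TFIIIA (GRMZM2G050939) had 7.06 ± 0.258 FPKM in WT and 6.89 ± 0.513 FPKM in fl3 (limma adjusted p = 0.719), and its log2 fold change of -0.23 passed under quantile normalization. The other measured PLATZ gene, PLTZ11 (GRMZM2G171934), did not pass, at 4.60 and 4.77 FPKM. No organellar ribosomal protein of the list reached the filter.

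Camera called none of the DNA replication, histone, auxin, endoplasmic reticulum, heat shock, ribosomal protein, translation, glycolysis, sugar or defense lists, with adjusted p (limma) from 0.13 for glycolysis to 0.918 for histones and sugar genes. For lists with no count of their own adjusted over the list alone in the text, that count was the same as over all genes. Median and test differed in sign for DNA replication, histones, basal transfer layer, heat shock proteins, storage regulators (medians above 0, camera direction down) and for aleurone genes (median -0.02, direction up). The means of the ribosomal protein, translation factor and sugar lists (0.04, 0.06 and 0.31) were above 0 while their medians and the camera direction were below.

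**Figure D3:**
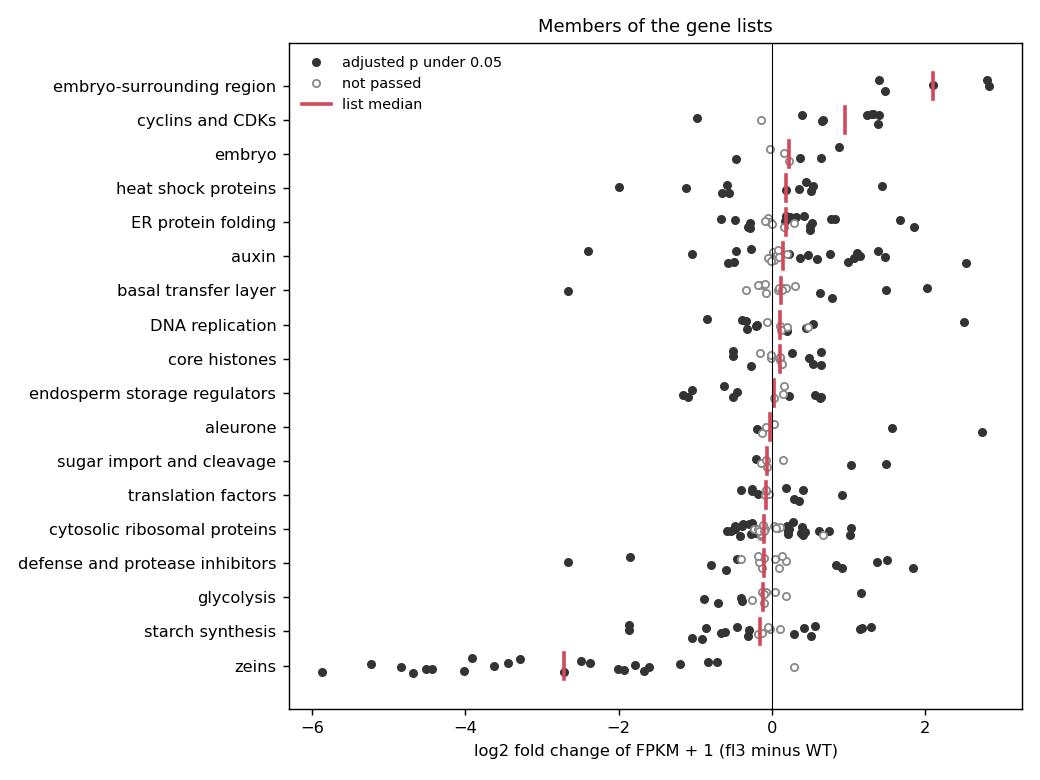
log2 fold changes (fl3 minus WT, FPKM + 1) of the measured members of 18 gene lists, 1 point per gene, filled where the limma adjusted p passed, with the list median as a red bar. Zeins lie to the left with a median of -2.71 and embryo-surrounding region markers to the right with a median of 2.11.

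Outside the zeins, the deepest fall of a named gene on the log2(FPKM + 1) scale was that of NRH3 (GRMZM2G104999), from 70.0 ± 1.06 to 4.07 ± 0.682 FPKM (SD, n = 3; 17.2-fold, limma adjusted p = 3.55e-08). The highest rises on that scale were those of HP3 (GRMZM2G451604; log2 fold change 3.33, 13.6-fold from 2.57 ± 0.104 FPKM, limma adjusted p = 2.18e-08) and the plasma-membrane aquaporin pip2b (GRMZM2G092125; log2 fold change 2.95, 9.03-fold), while the fold of means was higher for ae3 and mfs2 (GRMZM5G877788). The lipid transfer protein gene LTP3 (GRMZM2G126397), the actin Maz81 (GRMZM2G006765), mfs2, GP (GRMZM2G135893), TMT (GRMZM2G035213) and dehydroascorbate reductase dhar3 (GRMZM2G035502) rose by log2 fold changes between 2.47 and 2.81. Among genes without a name, GRMZM2G077718 went from 0.0309 to 209 FPKM and GRMZM2G107931 from 0.041 to 123.6 FPKM, while GRMZM5G833389 went from 219.8 to 0.682 FPKM and GRMZM2G179005 from 83.4 to 0.493 FPKM. Of the 10 genes of highest mean FPKM, 3 rose, 6 fell and 1, the glyceraldehyde phosphate dehydrogenase gpc4 (GRMZM2G176307), did not pass (log2 fold change -0.26, and called at -0.42 under median-of-ratios scaling), and 4 had no name. The 10 highest genes of each library held 9.76% ± 0.669 of the FPKM sum in WT and 6.97% ± 0.424 in fl3 (exact permutation p = 0.1, n = 3, the smallest possible).

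Called genes were spread over every chromosome. Of 12213 genes placed by the reference order, the share called ran from 65.0% on chromosome 5 to 72.7% on chromosome 4, and Fisher's exact test set these 2 apart from the rest (adjusted p = 0.00789 and 0.00775, Benjamini-Hochberg over 10 chromosomes). On chromosome 8, which carries floury3, the share was 66.3% against 68.8% elsewhere (adjusted p = 0.247 by Fisher's exact test). The densest window of 50 neighbours held 47 called genes and lay on chromosome 4, a count that 35 of 1000 shuffles reached (permutation p = 0.036), and 13 of those 47 were zein genes. Counting 2-fold changes, the densest window lay there too, with 26 genes, 13 of them zeins (0 of 1000 shuffles as high, permutation p = 0.001); with the zeins left out, a setting chosen after the data were seen, the densest window held 18, lay on chromosome 1 and did not pass (permutation p = 0.0909). At a mean of at least 5 FPKM the densest window of all calls held 46 and did not pass (permutation p = 0.171).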

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

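The counts of risen, fallen and 2-fold changed genes stayed within 1.5 times the main counts of 7519, 4107 and 2461 under every alternative but a filter at a mean of 5 FPKM, which tests fewer genes (4771 risen, 1289 changed at least 2-fold). Without 1 library at a time, 6920 to 7254 genes rose, 3672 to 3965 fell and 2451 to 2485 changed at least 2-fold. All 5841 genes risen under median-of-ratios scaling had also risen without it, and all 4107 fallen genes fell there too, among 5758. That scaling divides each library by a single factor and moved the median log2 fold change from 0.145 to 0.002, so this nesting largely follows from it. The lists called numbered 2 under every setting but an estimated correlation (0) and fry (10), which does not compare a list with other genes; fry also gave a direction opposite to camera for 7 lists: DNA replication (median log2 fold change 0.11) and sugar import and cleavage (-0.06), which it called, and basal transfer layer, core histones, ribosomal proteins, defense and translation factors, which it did not call. Without the filter on low values more members were tested, with 22 auxin and 10 defense genes up in place of 12 and 5. The floury3 gene stayed higher and called in every alternative, with log2 fold changes of 0.32 to 0.93, and the zein share stayed lower without any 1 library. Counting 2-fold genes, 4 chromosomes stood apart in place of 2; with the zeins also left out, a setting chosen after the data were seen, 3 did. Of 99 further named genes, 8 lost their call in at least 1 setting and grp1 (GRMZM2G080603, log2 fold change -0.46) changed sign under quantile normalization, at 0.04; the cause was not tested. A further 30 changes of sign concerned values with no call on either side.

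Leaving out 62 genes near 0 in 1 genotype, chosen after the data were seen, gave 7482 risen and 4082 fallen genes. With the replicate block, 7240 genes rose, 3897 fell and 2461 changed at least 2-fold, with 2 lists called, floury3 at 0.48 and the rise of dzs18 called (adjusted p = 0.0474). Deviations of same-numbered libraries correlated at -0.153, 0.072 and -0.023 and not every library correlated best with its own number, so the numbers were not taken as pairs. The planned count tests were not run, since read counts were not recovered; without them the depth behind low values stayed unknown.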

Other observations

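Families grouped by symbol were examined after the data were seen, and all tests in this part were likewise chosen after the results, except the placing of genes near floury3 and across chromosomes and the share with a single reference match among all other tested genes. Tubulins, the subunits of microtubules, were 9 up and 2 down of 13 in fl3, and 9 rose under each scaling tried. TUBB2 (GRMZM2G334899) rose from 14.7 ± 2.27 to 62.3 ± 0.667 FPKM (SD, n = 3), tub6 (GRMZM2G071790) from 122 ± 6.09 to 295 ± 20.2 FPKM and tua4 (GRMZM2G152466) from 532 ± 21.6 to 1160 ± 29.9 FPKM, each with a limma adjusted p under the threshold. Glutathione S-transferases, enzymes of detoxification, were 8 up and 2 down of 12, and 7 or 8 rose under each scaling; gst6 (GRMZM2G129357) rose from 7.89 ± 0.609 to 27.6 ± 1.63 FPKM and gst30 (GRMZM2G044383) fell from 8.54 ± 1.19 to 0.549 ± 0.176 FPKM. WRKY transcription factors were 9 up and 0 down of 11, with WRKY111 (GRMZM2G013391) at a log2 fold change of 1.11, and 4 up and 1 down under quantile normalization. Of 18 families tested with limma's camera 0 were called, with an estimated correlation 0, and 2, WRKY factors and tubulins, had an unadjusted p under 0.05 (adjusted p = 0.325 for each).

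The 6 libraries divide into 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 11626 called genes and 2461 changed at least 2-fold, the highest other split 0 and 0, so that 1 of the 10 splits reached each real count. For gene lists, 8 of the 10 splits called at least the 2 of the real split, the highest 5. Each other split sets 2 libraries of 1 genotype and 1 of the other against the reverse. Part of any difference between genotypes thus stays in the contrast, and the rest widens the spread within its groups. That spread alone can bring the gene calls of the other splits to 0, so these counts do not bear on chance. The zein list was called in 8 of the 9 other splits and the embryo-surrounding region list in 0. Lists not called between genotypes were called there too, the basal transfer layer in 5 and the defense and ribosomal protein lists in 3 each. Camera at the preset correlation can therefore call a list on variation between libraries of a genotype.

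The fall of the zein transcripts was weighed against 3 explanations. The tables argue against scaling to a library total filled by a few genes as the whole cause, since the median zein log2 fold change was -2.87 under median-of-ratios scaling. Reads moved between named near-identical copies would leave their sum in place, but the summed FPKM of named zeins fell by 1.39 on the log2 scale, with every fl3 library below every WT library. Gamma- and beta-zeins make up much of that sum. The alpha-zein sums fell as well, from 4586 to 169.9 FPKM for z1C and from 9093 to 1113 FPKM for z1A. Reads moved to copies without a name, or copies that differ between parents, were not tested. Slower development of the fl3 endosperm, with storage genes late and dividing cells persisting, is a candidate explanation that cannot be told apart from a direct effect of the mutation, because 1 age was sampled. The cyclin list had a median of 0.96 but camera did not call it (adjusted p = 0.127), and DNA replication genes (4 up, 6 down) and core histones (5 up, 3 down) went both ways, with medians of 0.11 each against 0.14 over all genes. Storage regulators (4 up, 6 down) and starch synthesis genes (7 up, 10 down) also went both ways, with o2, pbf1 and wx1 among those that fell. Camera called neither list. An effect of floury3 on the zein genes stays open as an untested hypothesis.

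The rise of the embryo-surrounding region markers was weighed against 2 explanations. A lower share of the main endosperm cells alone would raise markers of other compartments alike, but the median of the embryo-surrounding region lay 1.99 above that of the basal transfer layer on the log2 scale. An exact permutation test over 5 against 16 genes, which are not independent, gave p = 0.000688. The list was taken up because its members rose, so this p partly restates that choice and is no separate support. The basal transfer layer median ran from -0.18 without fl3 replicate 2 to 0.37 without fl3 replicate 3. With 1 list that varies within genotypes as the comparison, a lower share as part of the cause cannot be excluded. More tissue from beside the embryo in the fl3 dissections may account for it and cannot be told apart: the embryo list had a median of 0.23 with members going both ways (0.40 without fl3 replicate 2, 0.15 without fl3 replicate 1, 0.08 under median-of-ratios scaling), and such tissue can come without embryo. Only 7 of the 14 listed embryo genes passed the filter. Below it, lec1 (GRMZM2G011789), chosen after its values were seen, had means of 0.014 FPKM in WT and 1.25 FPKM in fl3, which were not tested. The highest group mean of the other embryo genes below it was 0.64 FPKM, for dhn1 in fl3. A larger or longer-lived region in fl3 was not tested. Slower development of the fl3 endosperm was not weighed for this rise and cannot be told apart either, because 1 age was sampled.

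In 62 genes the mean was under 0.1 FPKM in 1 genotype and every library of the other had at least 5 FPKM, 37 of them expressed in fl3 and 25 in WT. The tables argue against a donor segment around floury3 for the 20 genes with a place in the reference order, of which 0% lay within 250 tested neighbours of it (4.1% of all placed genes do) and 2 on its chromosome; for the 42 genes with no place it cannot be told apart. Differing parents across the genome are a candidate explanation: the placed genes lay on 9 chromosomes, and 32.3% of the 62 had a single reference match against 70.9% of other tested genes (Fisher's exact test, p = 4.02e-10) and 69.4% of genes of like mean FPKM. Neither value singles out this explanation. Effects of the mutation could be spread over chromosomes too, and the reference assembly differs from the build of the files, which can also lower the share matched. The labels used here give no pedigree of either genotype, so the genome-wide differences in expression may include some between parents as well as those of the mutation.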
